A study of Mus musculus with 8 samples.

How the data were processed

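Total RNA from the lungs of 8 mice, 4 of each genotype, was profiled by CAGE. Per the labels, RNA of integrity number above 7.0 was reverse transcribed, cap-trapped and barcoded, and the 8 libraries were sequenced together as single-end reads of 75 nt on an Illumina NextSeq 500. The submitters' processing notes name BWA 0.7.12-r1039, HISAT2 2.0.5, edgeR and the genome build mm9, without their role or order. How CAGE tags were assigned to genes, whether strand was used, and with which annotation, are not given in the sources used here. Groups and replicate numbers were taken from the labels, which describe separate animals but give no sex, litter, time of collection or library batch.

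The values deposited by the authors are counts per 1000000 reads (CPM) with 2 decimals for 15728 genes, and from the values each column adds up to 1000000 within rounding, so no scaling between libraries beyond the total is visible. In each library the values were whole multiples of 1 step, the CPM of 1 read. Reads and library totals were recovered from these steps, and 100% of values came out whole within 0.1 reads. Totals were 13014134 to 18593913 reads, and 3 reads, used as the floor for a gene at 0, correspond to 0.161 to 0.231 CPM. That floor covers counting error only, since CAGE reads without molecular identifiers need not be independent molecules. Pairs of libraries of the same genotype differed by a chi-square of 11.64 to 19.77 per gene, beyond counting noise, so no 2 agreed as repeated sequencing of 1 library would. Separate libraries from the same RNA are not excluded by this.

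The main test was fixed before the data were examined. Genes with at least 1 CPM in at least 4 of the 8 libraries (14065) were tested on log2(CPM + 0.5) with limma 3.58.1 in R 4.3.3, with a variance trend on mean level, genotype as the only term and the deposited CPM as they are. Adjusted p are Benjamini-Hochberg values, two-sided, over all genes tested, and a gene was called at an adjusted p under 0.05. Each adjusted p of a gene comes from this limma fit unless another tool is named. The test was also run on simulated data drawn from the means and library sizes of this comparison (13998 genes). It recovered 46 of 67 genes changed 1.5-fold, 63 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 11 false calls among 13865 unchanged genes. The spread between animals was set by a formula and not estimated from these data. Genes varied independently and few were changed, so these rates are only a guide.

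A set of 52 gene lists of pathways and cell types and 2 check lists, of sex-linked genes and of genes that differ between strains, was also fixed before the data were examined. Lists with at least 5 measured members were tested with camera of limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 52 lists, and again with the correlation estimated for each list. Counts adjusted over the list alone use Benjamini-Hochberg values over the members of a list. The check lists were read gene by gene.

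The rule for the genes named in the text, also fixed beforehand, took the Nos genes, the 10 called genes with the largest rise and the 10 with the largest fall, every called Wnt gene, the check lists, and called members of each list with the smallest adjusted p. The 10 largest needed a mean of at least 5 CPM, no overlap between genotypes and a name that does more than number a gene model. How many members were named was narrowed after values were seen, to 4 for lists that camera called and 2 for the others. Also chosen after their values were seen were Sftpc, Sftpb, Scgb1a1, Ctnnb1, Wnt2, Wnt5a, Tppp3, Eln, Gucy1a1, Cd79a, Gm6166, Gm8210, Gm10709, Gm13841, Ube2c, Cdc20, Prc1, Ccna2, Cdkn2a, Adm and the clock genes outside the rule. In all 193 genes were named and followed through the alternatives. Some genes that the rule would name are not reported here.

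Gene names were looked up by Ensembl identifier in GENCODE M21 (GRCm38). It holds 15066 of the identifiers and lacks 662, and for 1666 its symbol is newer than the deposited one. The current symbols decided whether a name only numbers a model: Rps15a-ps6, Atp6v0c-ps2, Zfp984, Smim6 and Ciart are listed by the authors as Gm11968, Gm15487, Gm13157, 1110017F19Rik and Gm129. Chil1 is listed as Chi3l1 and Gucy1a1 as Gucy1a3. Because the reads were placed on mm9, this reference was used only for names, for which genes neighbour or overlap each other and for copies, and no coordinates are given. The first 200 nt of transcripts of 14973 genes were compared with blastn 2.17.0. A copy of at least 97% identity over at least 75 nt was found for 1690, and for 1165 of them a copy was listed. Another 359 entries fell into sets with identical values, 184 of them repeating another.

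Values of genes that overlap another listed gene are uncertain, since the use of strand is not given. This holds for 3830 genes, and among the named ones for Rps15a-ps6, Ly6k, Gpx2-ps1, Stk32c, Smim6, Ciart, Wdfy1, Tcf7l1, Csnk2b, Adam17, Abca3, Ccdc39, Tagln, Gja5, Folr2, Fcrla, Myh7, Mns1, S100b, Ccne2, Il1a, Dusp1, Pdia3, Rps3, Ctnnb1, Dbp, Per3, Nr1d1, Cdc20, Prc1 and Ccna2.

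Alternatives fixed beforehand were a pseudocount of 0.1 or 2 CPM, no filter or a mean of at least 5 CPM, median-ratio scaling, quantile normalization, array weights, a robust variance prior, the replicate number as a block, each library left out in turn, and edgeR 4.0.16 or DESeq2 1.42.0 on the recovered reads. Added after the data were seen were identical entries collapsed to 1, reads thinned to the smallest library, and genes with a near-identical copy left out. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9. Start sites within genes, enhancers and single reads were not analysed here.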

Results

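Lung gene expression was measured by cap analysis of gene expression (CAGE), which sequences the capped 5′ ends of RNA and so counts transcripts at their start sites. The lungs came from 4 wild type mice and 4 mice lacking the neuronal, inducible and endothelial nitric oxide synthases, all labelled as on a C57BL/6J background, 4 weeks old and unexposed. The deposited table listed 15728 genes in counts per 1000000 reads (CPM). Library totals recovered from the CPM steps ran from 15598154 to 18593913 reads in wild type and from 13014134 to 15096188 reads in the knockout. All knockout libraries were thus shallower than all wild type libraries. A gene at 3 reads had a CPM of 0.161 to 0.231, depending on the library. Scgb1a1, the main secretory protein of club cells, and Sftpc, a surfactant protein of alveolar type 2 cells, were the most abundant transcripts, with means over the 8 libraries of 86503 and 58072 CPM. Values below are means ± SD of CPM over the 4 animals of a genotype. Log2 fold changes, given as knockout minus wild type on log2(CPM + 0.5), understate the change of genes with low values.

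The comparison asked which transcripts differ in the lung when all 3 nitric oxide synthase genes are missing. Nos3, the endothelial isoform, stood at 18.2, 22.8, 19.8 and 18.6 CPM in the 4 wild type libraries and at 5.56, 8.32, 8.83 and 6.76 CPM in the 4 knockout libraries. It fell by 1.39 on the log2 scale (SE 0.137, limma adjusted p = 4.58e-05). CAGE reads lie at the start of the transcript, and where they lie relative to the deleted part of Nos3 is not given in the sources used here, so the remaining signal is a weak check of the genotype. Nos1 and Nos2 had no row in the table used here and were not analysed.

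Across 14065 genes with at least 1 CPM in at least 4 libraries, 2341 were higher and 2010 lower in the knockout. Together they were 30.9% of the genes tested. Counts of called list members below are to be read against that share, which several lists do not exceed. Most changes were small: the median absolute log2 fold change of the called genes was 0.42, a 1.34-fold difference. More than 1 on the log2 scale separated the genotypes for 160 of the higher and 196 of the lower genes. The genotypes did not overlap for 4382 genes (31.2%), where chance gives 2.9%. The main axis of a principal component analysis held 62.5% of the variance and parted the 4 knockout from the 4 wild type libraries. Count tests on the reads recovered from the CPM called 2247 genes higher and 2326 lower with edgeR, and 2189 and 2266 with DESeq2.

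Among the genes with the largest increases and a mean of at least 5 CPM, with no overlap between genotypes and genes known only by a model number left out, Psca, a membrane-anchored surface protein, went from 0.11 ± 0.15 to 50.9 ± 19.2 CPM (adjusted p = 3.09e-08). Its Ly6 family relative Ly6k went from 0.98 ± 0.37 to 42.8 ± 16.1 CPM. Dmkn, the secreted epithelial protein dermokine, went from 11.7 ± 1.97 to 228 ± 53.1 CPM (adjusted p = 1.94e-08). Spon2, a secreted matrix protein, rose by 2.74 on the log2 scale, and the kinase gene Stk32c by 3.37. Arntl and Npas2, which encode partner activators of the circadian clock, were also among these genes. Processed pseudogenes made up the rest: Rps15a-ps6 went from 0.56 ± 0.27 to 232 ± 73 CPM, Atp6v0c-ps2 from 0.16 ± 0.28 to 75.4 ± 7.55 CPM and Gpx2-ps1 from 0.38 ± 0.07 to 19.1 ± 2.8 CPM.

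The largest decreases under the same limits were led by Nppa, which encodes atrial natriuretic peptide and went from 63.1 ± 25.1 to 0.07 ± 0.06 CPM (adjusted p = 1.81e-08). Fabp5, a fatty acid binding protein, went from 241 ± 19.2 to 4.54 ± 0.27 CPM, and the ribosomal protein genes Rpl29 and Rplp1 went from 241 ± 29.2 to 6.46 ± 0.54 CPM and from 996 ± 179 to 87.2 ± 1.69 CPM. Ceacam10 averaged 11 ± 0.52 CPM in wild type and had 0 reads in all 4 knockout libraries, which put it at least 210-fold lower against a floor of 3 reads over the group. The zinc finger genes Zfp984 and Zfp942, the ribonuclease gene Rnaset2b, the small membrane protein gene Smim6 and the clock repressor Ciart also fell. Their log2 fold changes were -4.02, -3.52, -3.74, -3.67 and -3.57. Copies of at least 97% identity over at least 75 nt near the 5′ end were listed for Rps15a-ps6, Atp6v0c-ps2, Gpx2-ps1, Fabp5, Rpl29, Zfp984 and Rplp1. How reads were divided between copies makes these values uncertain. Copies that the authors did not list are not named here, so values of the other genes above can be uncertain too. Gm6166, the listed copy of Fabp5, rose from 0.17 ± 0.31 to 138 ± 16 CPM, and Gm8210, a listed copy of Rpl29, rose from 1.13 ± 1.35 to 513 ± 43.9 CPM. Other listed copies of Rpl29 fell, Gm13841 from 44.1 ± 8.35 to 0.64 ± 0.39 CPM and Gm10709 from 152 ± 24.2 to 0.06 ± 0.04 CPM. Gm10709 had 3 reads in knockout and 10282 in wild type, a ratio of 2883 (95% counting interval 986 to 13981). That interval covers counting error only. Summed over Rpl29 and its listed copies, the mean was 438 CPM in wild type and 519.8 CPM in the knockout, so the sum did not fall. Gm6166, Gm8210, Gm13841 and Gm10709 were named after their values were seen.

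**Figure D1:**
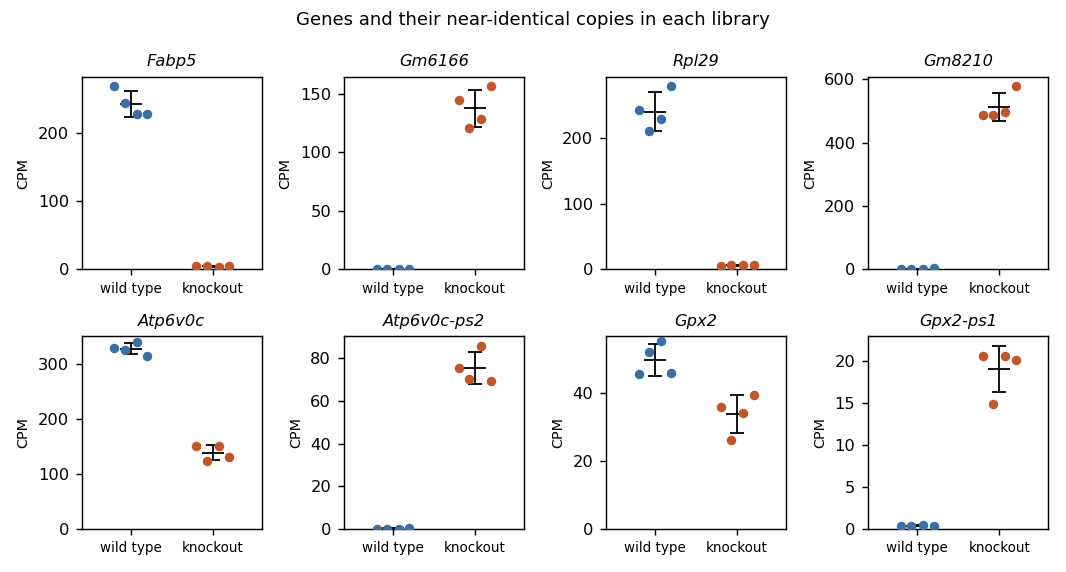
Dots show CPM in each library for genes (left of each pair) and near-identical copies (right), with mean and SD as black bars over 4 libraries per genotype, wild type in blue and knockout in orange, each axis starting at 0. Fabp5 averaged 241 CPM in wild type and 4.54 CPM in the knockout, while Gm6166 averaged 0.17 and 138 CPM.

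Sfrp2, a secreted Wnt antagonist, fell from 27.5 ± 6.34 to 3.16 ± 1.06 CPM (adjusted p = 7.03e-06), and Apcdd1, a membrane-bound antagonist that Wnt signalling also induces, fell from 8.46 ± 0.85 to 3.34 ± 0.33 CPM. They were the called genes among 11 antagonists. Among 11 ligands, Wnt4 fell by 0.77 and Wnt9a by 0.56 on the log2 scale, and Wnt7a rose by 0.56. Wnt2 stood at 24.4 ± 3.24 CPM in wild type and 26.1 ± 4.81 CPM in the knockout. Wnt5a stood at 7.72 ± 1.82 CPM in wild type and 7.31 ± 1.14 CPM in the knockout. Of 16 receptors and coreceptors, Ryk (from 28.3 ± 1.84 to 16.6 ± 2.25 CPM), Ptk7 and Fzd1 fell and Fzd6 rose, and 5 fell without knockout replicate 2. The Wnt lists were included because the study's published account of these lungs names the pathway, so their counts are not independent evidence of a direction. Leaving out wild type replicate 2 ended the call of Wnt7a (adjusted p = 0.00782 to 0.0504 over all alternatives). Leaving out any library except knockout replicate 1 or 2 ended that of Fzd1 (adjusted p = 0.00554 to 0.0924).

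Of 52 measured genes for Wnt secretion and signal transduction, 11 rose and 13 fell. Those that fell included the ligand acyltransferase Porcn (from 17 ± 0.34 to 11.3 ± 1.04 CPM), the kinase genes Gsk3a, Gsk3b, Csnk1e and Csnk1g2, the scaffold genes Axin1 and Dvl1, the transcription factors Lef1, Tcf7 and Tcf7l1, the corepressor Tle1, the coactivator Crebbp and the ligand enhancer Rspo1. Those that rose were Tcf7l2 (from 34.6 ± 3.37 to 50.4 ± 5.49 CPM), Rspo3, Rspo4, Daam1, Daam2, Chd8, Csnk1g1, Csnk2b, Prickle1, Vangl2 and Tle2. The calls of 5 of these genes ended when 1 library was left out. Rspo4 lost it without wild type replicate 2 (adjusted p = 0.0129 to 0.0639 over all alternatives) and Rspo1 without wild type replicate 2, 3 or 4 (0.00978 to 0.0596). Csnk2b lost it without wild type replicate 1, 2 or 4 or knockout replicate 3 or 4 (adjusted p = 0.0242 to 0.106), Tle2 without any library except knockout replicate 4 (0.0205 to 0.103) and Crebbp without any of the 8 (0.0245 to 0.106). Ctnnb1, the gene of β-catenin, stood at 261 ± 49 CPM in wild type and 240.3 ± 57.5 CPM in the knockout (adjusted p = 0.578).

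Among 21 Wnt target genes, 3 rose and 4 fell. Sp5 and Vegfa rose, by 0.92 and 0.54 on the log2 scale. Axin2 rose from 11.5 ± 1.69 to 14.8 ± 1.59 CPM (adjusted p = 0.0366), and Apcdd1, Lef1, Tcf7 and Sox9 fell. Lef1 and Tcf7 are also expressed in lymphocytes, and the list of T and NK cell genes was called lower as well (median log2 fold change -0.25, camera adjusted p = 0.011; adjusted p = 0.92 with an estimated correlation). The call of Axin2 ended without wild type replicate 1, 2 or 3 or knockout replicate 2 or 4 (adjusted p = 0.0118 to 0.0955 over all alternatives). Counts of genes that rose and fell, adjusted over the list alone, were 1 and 2 for ligands, 1 and 3 for receptors, 11 and 16 for signal transduction, 0 and 2 for antagonists, and 3 and 4 for targets. Tested against other genes with limma's camera, none of the Wnt lists passed. The adjusted p were 0.59 for ligands, 0.19 for receptors, 0.33 for signal transduction, 0.24 for antagonists and 0.89 for targets. For target genes the median log2 fold change was positive (0.03) and the camera direction was down.

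**Figure D2:**
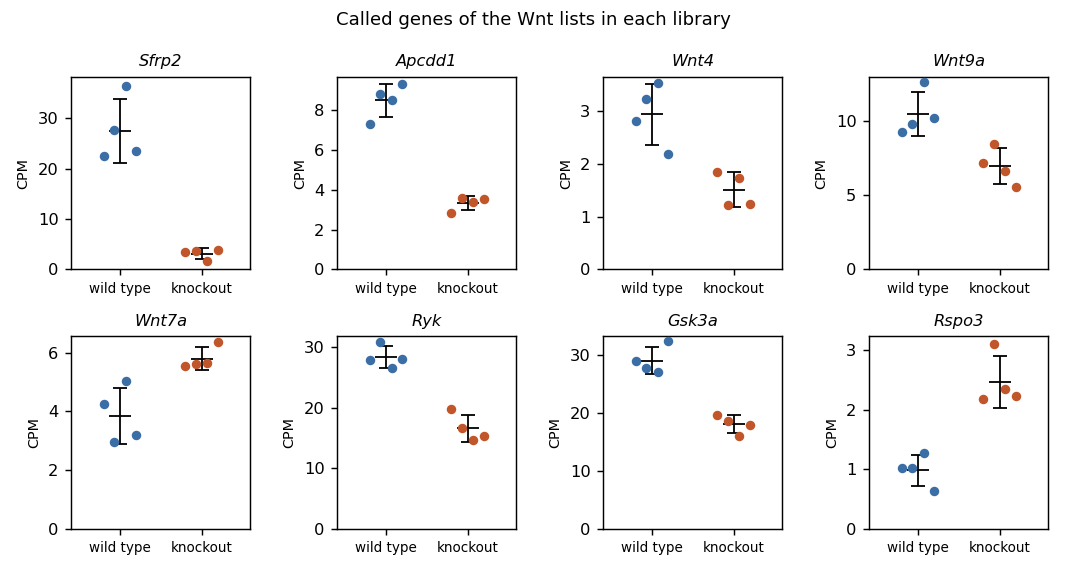
Dots show CPM in each of 4 wild type (blue) and 4 knockout (orange) libraries for called genes of the Wnt lists, with mean and SD as black bars and each axis starting at 0. Sfrp2 averaged 27.5 CPM in wild type and 3.16 CPM in the knockout, and Rspo3 averaged 0.99 and 2.47 CPM.

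All 20 measured circadian clock genes changed, in different directions for different arms of the clock. The activators Arntl (from 2.36 ± 0.32 to 18.1 ± 7.28 CPM, adjusted p = 0.000135), Npas2 and Clock (from 33.2 ± 0.82 to 61.7 ± 6.25 CPM) rose together with the repressor gene Nfil3. Genes that these activators drive fell, with Dbp going from 90.2 ± 8.49 to 14.2 ± 17.4 CPM, Hlf from 34.5 ± 2.73 to 4.52 ± 2.46 CPM, Ciart from 12.2 ± 1.07 to 0.72 ± 0.81 CPM and Per3 from 64 ± 3.92 to 15 ± 9.93 CPM. The remaining clock genes also fell. Per1, Per2, Cry1, Cry2, Nr1d1, Nr1d2, Tef, Bhlhe40, Bhlhe41, Usp2 and Rora, a receptor gene whose product drives Arntl, were among them. In this list 4 genes rose and 16 fell, and the same counts were found adjusted over the list alone. The list was called lower (camera adjusted p = 0.00024; adjusted p = 0.92 with an estimated correlation). Knockout replicate 1 stood apart from the other knockout libraries: Arntl was 7.22 CPM in it and 20.5 to 22.8 CPM in the other 3. With each clock gene turned by its own direction of change, its mean shift from wild type was 0.94 on the log2 scale against 1.9, 1.86 and 1.97. Without knockout replicate 1 the log2 fold change of Dbp was -3.90 in place of -3.21, and the list kept its call (adjusted p = 2.43e-06; 2.43e-06 to 0.923 over all alternatives). Leaving out 1 library ended the calls of Nr1d1 for all libraries except knockout replicate 1 (adjusted p = 0.000588 to 0.116 over all alternatives). The same held of Rora for wild type replicates 1 to 3 and knockout replicates 1, 3 and 4 (0.00826 to 0.114), and Cry2 for wild type replicates 3 and 4 (0.00518 to 0.0631).

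**Figure D3:**
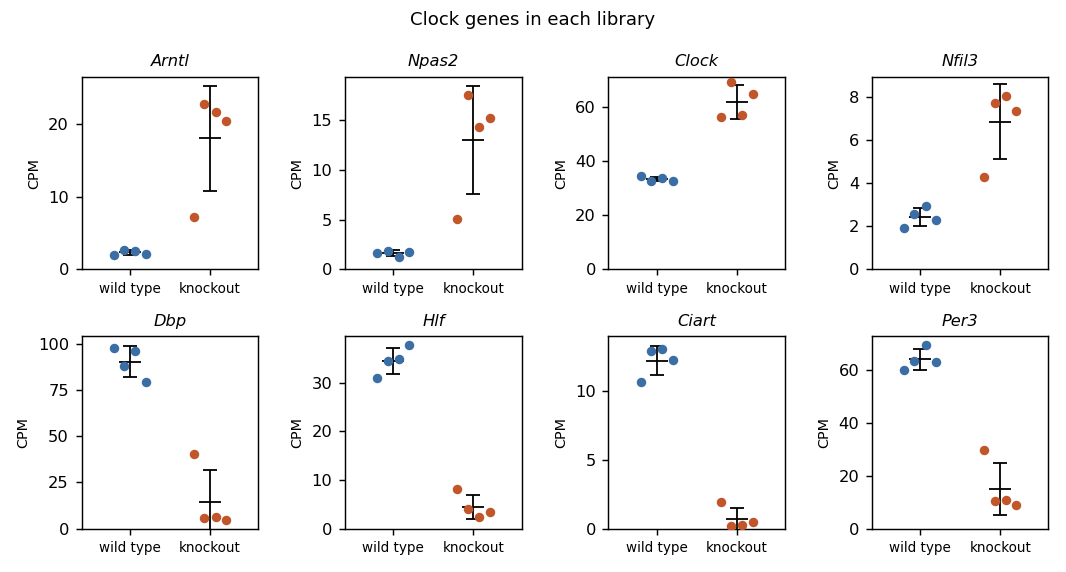
Dots show CPM in each of 4 wild type (blue) and 4 knockout (orange) libraries for clock genes, with mean and SD as black bars and each axis starting at 0. Arntl was 7.22 CPM in knockout replicate 1 and 20.5 to 22.8 CPM in the other knockout libraries, all above the wild type mean of 2.36 CPM.

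Alveolar type 2 genes went both ways. Chil1, a chitinase-like secreted protein, fell from 1363 ± 95.3 to 192 ± 32 CPM (adjusted p = 1.81e-08), and the surfactant protein gene Sftpc fell from 75406 ± 7581 to 40739 ± 4973 CPM, a call that ended with quantile normalization (adjusted p = 0.171; 7.42e-17 to 0.171 over all alternatives). Quantile normalization gives each rank the same value in every library. Sftpc was, with Scgb1a1, the most abundant transcript, so a fall of it can hardly show under that step. Abca3, the lipid transporter of lamellar bodies, rose from 165 ± 7.49 to 313 ± 21.5 CPM. Of 24 such genes, 3 rose and 9 fell. Sftpb stood at 1233 ± 124 CPM in wild type and 1219 ± 179 CPM in the knockout. Among 20 alveolar type 1 genes 5 rose and 4 fell, with Vegfa rising from 1101 ± 27.2 to 1608 ± 133 CPM and the membrane glycoprotein gene Pdpn falling from 195 ± 25.7 to 109.8 ± 13 CPM. With p adjusted over the list alone, the counts that rose and fell were 3 and 9 for type 2 cells and 5 and 4 for type 1 cells. Neither list was called by camera, with adjusted p of 0.19 for type 2 cells and 0.96 for type 1 cells.

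The airway cell genes that passed the test fell. Of 22 ciliated cell genes 14 fell (16 adjusted over the list alone), including Foxj1, the transcription factor of motile cilia (from 85.1 ± 3.69 to 51.7 ± 4.66 CPM). Of the others, Rsph1, a gene of cilium structure, fell from 78.2 ± 5.57 to 44.8 ± 2.1 CPM, Tmem212 fell from 103 ± 7.38 to 18.6 ± 3.05 CPM (adjusted p = 3.78e-08), and Ccdc39 was also lower. Tppp3, another gene of this list, stood at 498 ± 19.2 CPM in wild type and 504 ± 50.3 CPM in the knockout. Club and secretory genes fell for 10 of 17 members, including the mucin gene Muc5b (from 38.8 ± 9.79 to 17.9 ± 2.36 CPM), Gabrp, Gsta3 and Ces1f. Scgb1a1 stood at 83216 ± 9650 CPM in wild type and 89790 ± 11500 CPM in the knockout (adjusted p = 0.546). Adjusted over the list alone, 1 club gene rose and 11 fell. Camera called both lists lower. The values were adjusted p = 1.3e-06 for ciliated cells (adjusted p = 0.74 with an estimated correlation) and adjusted p = 0.008 for club cells (adjusted p = 0.92 with an estimated correlation).

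**Figure D4:**
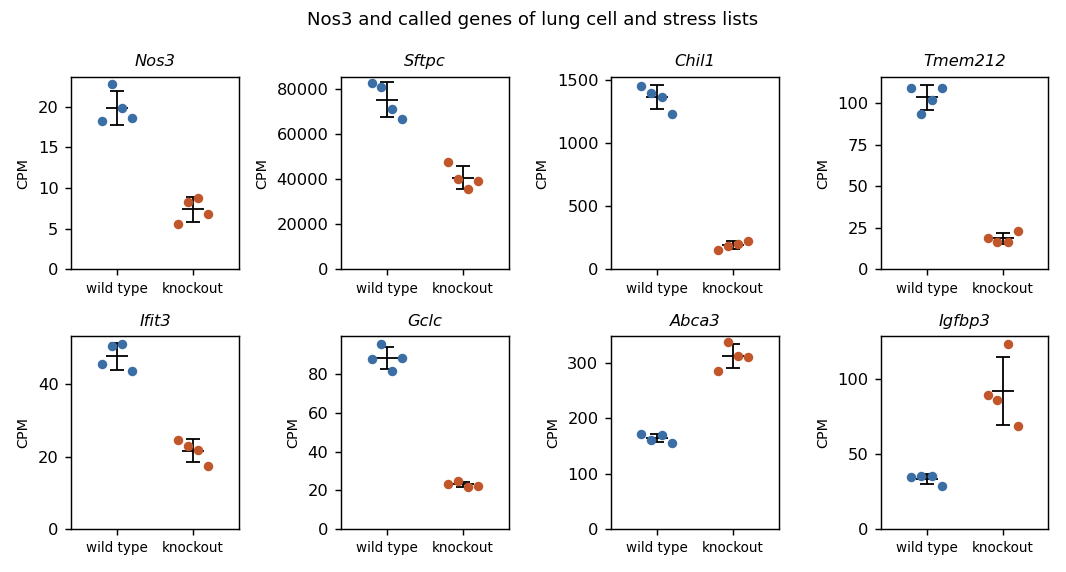
Dots show CPM in each of 4 wild type (blue) and 4 knockout (orange) libraries for Nos3 and for called genes of lung cell and stress lists, with mean and SD as black bars and each axis starting at 0. Chil1 averaged 1363 CPM in wild type and 192 CPM in the knockout, and Abca3 averaged 165 and 313 CPM.

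The interferon response genes that passed the test were mostly lower. Ifit3 fell from 47.8 ± 3.72 to 21.6 ± 3.1 CPM (adjusted p = 2.95e-05), Ifit1 from 21.5 ± 1.56 to 12.4 ± 0.78 CPM, Oasl2 from 32.8 ± 1.87 to 22.1 ± 1.99 CPM and Isg15 from 107 ± 5.83 to 79.3 ± 4.85 CPM. These are antiviral genes induced by type I interferon. Ifit3 has the near-identical listed copy Ifit3b. Among 33 members 20 fell and 2 rose (21 and 2 adjusted over the list alone), with 0 or 1 higher when any library except knockout replicate 1 was left out. Camera called the list lower (adjusted p = 6.7e-06; adjusted p = 0.39 with an estimated correlation). Antioxidant genes fell for 13 of 39 members and rose for 5. Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis, fell from 88.5 ± 5.84 to 23 ± 1.31 CPM (adjusted p = 1.29e-08), and the glutathione transferase Gsta1, which has the listed near-identical copy Gsta2, fell from 5.36 ± 0.42 to 1.39 ± 0.44 CPM. The antioxidant list missed the threshold (camera adjusted p = 0.051) and passed it under several alternatives, among them leaving out knockout replicate 1 (adjusted p = 0.015; 0.00927 to 0.923 over all alternatives), 3 or 4 or wild type replicate 1, 3 or 4. Only 3 antioxidant genes rose without knockout replicate 1, 3 or 4 or wild type replicate 2 or 4, or with median-ratio scaling or quantile normalization. Of 21 inflammatory genes 8 rose and 3 fell. The cytokine Il1a rose from 1.08 ± 0.29 to 4.48 ± 0.98 CPM and the alarmin Il33 fell from 97.9 ± 15.1 to 60.7 ± 9.18 CPM (camera adjusted p = 0.16). In counts adjusted over the list alone, 5 antioxidant genes rose and 14 fell, and 11 inflammatory genes rose and 4 fell.

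The lymphocyte genes that passed the test fell. Of 20 B and plasma cell genes 6 fell (7 adjusted over the list alone), among them Fcer2a. Fcrla fell from 4.24 ± 0.28 to 1.51 ± 0.59 CPM and Vpreb3 from 48.1 ± 3.31 to 24.4 ± 8.12 CPM. Knockout replicate 1 held the highest value of Cd79a among knockout libraries, 87.1 CPM, against 44.2, 37.2 and 23.3 CPM, and without it 14 genes of the B cell list fell. Of 23 T and NK cell genes 5 fell, including the T cell receptor subunit gene Cd3g (from 15.4 ± 1.58 to 10.7 ± 1.08 CPM), the chemokine Ccl5, the kinase gene Lck and Nkg7 (3 adjusted over the list alone). The call of Nkg7 ended without any library except wild type replicate 3 or knockout replicate 1 (adjusted p = 0.0143 to 0.105 over all alternatives). Only 3 T and NK cell genes fell with quantile normalization, at a mean of at least 5 CPM or without wild type replicate 1 or 2 or knockout replicate 3 or 4, against 8 without knockout replicate 1 and 9 with array weights. Camera called B cells (adjusted p = 0.01; adjusted p = 0.92 with an estimated correlation) and T and NK cells (adjusted p = 0.011; adjusted p = 0.92 with an estimated correlation) lower. The call of B cells ended at a mean of at least 5 CPM, with 2 genes lower (adjusted p = 0.149; 2.33e-05 to 0.923 over all alternatives).

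Erythroid and platelet genes fell for 9 of 16 members and rose for 1 (10 and 1 adjusted over the list alone). The red cell enzyme gene Bpgm fell from 64.5 ± 8.14 to 42.2 ± 3.27 CPM and the platelet chemokine gene Ppbp from 7.27 ± 0.7 to 3.17 ± 1.2 CPM. Camera called the list lower (adjusted p = 0.008; adjusted p = 0.92 with an estimated correlation). Striated and cardiac muscle genes split. Of these, 6 of 20 fell, led by Nppa, the oxygen-binding protein Mb (from 15.3 ± 3.56 to 3.35 ± 0.72 CPM) and Ckmt2. The 2 that rose included the myosin gene Myh7 (from 10.5 ± 0.21 to 30 ± 0.69 CPM). The counts were the same adjusted over the list alone. That list passed in camera (adjusted p = 0.04; adjusted p = 0.92 with an estimated correlation). Its call ended without wild type replicate 4 (adjusted p = 0.103) and without knockout replicate 3 (adjusted p = 0.115; 0.011 to 0.923 over all alternatives), and also with median-ratio scaling and at a mean of at least 5 CPM.

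Of 14 neutrophil genes 4 fell, with the lactoferrin gene Ltf falling from 14.8 ± 2.74 to 6.57 ± 2.81 CPM and Stfa2l1 from 3.93 ± 1.48 to 1.34 ± 0.4 CPM (camera adjusted p = 0.051). Among 19 alveolar macrophage genes 6 rose and 1 fell. The gene that fell was Bhlhe41 (from 26.3 ± 1.96 to 11.5 ± 2.19 CPM), which is also in the clock list. The lipid transporter gene Abcg1 rose from 35.9 ± 3.77 to 54.2 ± 3.61 CPM. Interstitial macrophage and monocyte genes rose for 2 and fell for 3 of 24, with Folr2 and Lyve1 lower. Dendritic cell genes rose for 5 and fell for 3 of 17. The class II antigen presentation genes H2-Ab1 and H2-Aa rose from 482 ± 35.7 to 754 ± 63.4 CPM and from 127 ± 11.7 to 178 ± 12.2 CPM. In the list of 5 mast cell, basophil and eosinophil genes the mast cell protease gene Cma1 rose from 0.98 ± 0.12 to 1.71 ± 0.43 CPM. The call ended without wild type replicate 1, 2 or 4 or knockout replicate 1, 2 or 3 (adjusted p = 0.009 to 0.0884 over all alternatives). Adjusted over the list alone, the counts that rose and fell were 0 and 4 for neutrophils, 6 and 1 for alveolar macrophages, 2 and 3 for interstitial macrophages, 5 and 3 for dendritic cells and 1 and 0 for mast cells. Camera gave adjusted p of 0.23 for alveolar macrophages, 0.8 for interstitial macrophages, 0.87 for dendritic cells and 0.64 for mast cells. The neutrophil list was called without knockout replicate 1 (adjusted p = 0.029; 0.00717 to 0.923 over all alternatives) or 4, or wild type replicate 3 or 4.

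Matrix genes that passed the test were mostly higher. Of 42 collagen and matrix genes 11 rose and 1 fell, with the collagen lysyl hydroxylase Plod1 rising from 28.6 ± 3.06 to 76.4 ± 7.7 CPM (adjusted p = 1.97e-06) and Col15a1 from 2.61 ± 0.59 to 7.29 ± 1.83 CPM. The list missed the threshold (camera adjusted p = 0.051) and passed it without knockout replicate 1 (adjusted p = 0.00475; 0.00475 to 0.923 over all alternatives) or 3 or wild type replicate 3 or 4. Only 7 of its genes rose without knockout replicate 2 or 3. Elastic fibre genes rose for 7 of 24 members, led by Emilin2 (from 12.2 ± 2 to 23.2 ± 3.46 CPM), and fell for 1, Loxl4 (from 2.66 ± 0.2 to 1.52 ± 0.09 CPM). Elastin itself, Eln, stood at 183 ± 49.3 CPM in wild type and 285 ± 127 CPM in the knockout (adjusted p = 0.223). It was 121 CPM in knockout replicate 1 and 266 to 426 CPM in the other 3. Without that library Eln was called higher (adjusted p = 0.00706; 0.00706 to 0.483 over all alternatives). Matrix protease genes rose for 8 and fell for 2 of 28, with the membrane protease genes Adam17 and Mmp14 rising from 47 ± 1.58 to 77.5 ± 9.03 CPM and from 53.1 ± 1.55 to 76.8 ± 8.29 CPM. Among 15 antiprotease genes 4 rose, including the serpin genes Serpina3n (from 30 ± 0.94 to 51.7 ± 11.7 CPM) and Serpinb1a, and 2 fell, or 0 without wild type replicate 3, 1 without knockout replicate 2 and 4 with median-ratio scaling or edgeR. Adjusted over the list alone, the counts that rose and fell were 11 and 1 for collagens, 7 and 1 for elastic fibres, 8 and 2 for proteases and 4 and 4 for antiproteases. Only 5 protease genes rose without knockout replicate 3 or wild type replicate 1, 2 or 4, and 1 fell without wild type replicate 1 or 3. The last 3 of these lists were not called (camera adjusted p of 0.42 for elastic fibres, 0.33 for proteases and 0.8 for antiproteases).

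Genes of mesenchymal cells went both ways. Pdgfra, a growth factor receptor of alveolar fibroblasts and myofibroblasts, rose from 92 ± 4.34 to 130.2 ± 0.85 CPM, whereas the fibroblast transcription factor Tcf21 fell from 61.4 ± 3.37 to 39.5 ± 3.59 CPM. The counts that rose and fell, out of those measured, were 5 and 4 of 19 for alveolar fibroblasts and 5 and 4 of 19 for adventitial fibroblasts (Htra3 rose, C3 fell). They were 4 and 3 of 17 for myofibroblasts and 6 and 5 of 24 for smooth muscle and pericytes. In the muscle lists Tagln, a cytoskeletal protein, fell from 88.9 ± 2.03 to 60.6 ± 10.3 CPM, and the pericyte gene Rgs5 and the integrin gene Itga7 rose from 9.97 ± 0.66 to 29.1 ± 10.1 CPM and from 13.2 ± 0.19 to 24.9 ± 4.39 CPM. Mesothelial genes rose for 1 (Aldh1a2) and fell for 3 of 12. Adipocyte genes rose for 2 and fell for 4 of 14, with the lipid synthesis genes Acsl1 and Dgat2 falling from 38 ± 2.33 to 20.2 ± 1.87 CPM and from 15.2 ± 2.86 to 6.53 ± 3.1 CPM. The numbers that rose and fell adjusted over the list alone were 8 and 4 for alveolar fibroblasts, 5 and 4 for adventitial fibroblasts, 4 and 3 for myofibroblasts, 6 and 5 for smooth muscle, 2 and 3 for mesothelium and 2 and 5 for adipocytes. Only 2 alveolar fibroblast genes rose without wild type replicate 1 or knockout replicate 3, and 3 without wild type replicate 4 or knockout replicate 2. Smooth muscle genes fell for 3 members without wild type replicate 1 or 3 or knockout replicate 3, and myofibroblast genes for 1 without wild type replicate 3 or knockout replicate 3. Mesothelial genes fell for 1 without wild type replicate 2, 3 or 4. Adipocyte genes fell for 2 without wild type replicate 1, 2 or 3 or knockout replicate 2 or 3, and rose for 1 when any library except knockout replicate 2 was left out and with median-ratio scaling or quantile normalization. None of these lists passed in camera, with adjusted p of 0.87 for alveolar fibroblasts, 0.58 for adventitial fibroblasts, 0.95 for myofibroblasts, 0.83 for smooth muscle, 0.87 for mesothelium and 0.19 for adipocytes.

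Endothelial genes also divided. Aplnr, the apelin receptor of general capillaries, rose from 51.9 ± 4.86 to 95.9 ± 11.1 CPM. Sema3c rose from 270.2 ± 17.9 to 399.8 ± 38.5 CPM, and the arterial connexin gene Gja5 rose by 0.59 on the log2 scale. General capillary genes rose for 6 and fell for 3 of 23, or 7 and 6 with median-ratio scaling and 6 and 6 with quantile normalization. Aerocyte genes did so for 2 and 4 of 18 (Sirpa and Ednrb rose), and arterial, venous and lymphatic genes for 7 and 4 of 20, or 4 higher without wild type replicate 2. Genes of nitric oxide and cGMP signalling other than the synthases rose for 3 and fell for 4 of 32, with 1 higher without wild type replicate 1. Together this lay below the share of 30.9% called over all genes. Npr2, a natriuretic peptide receptor whose row repeats the values of another, fell from 18.1 ± 1.95 to 10.8 ± 1.68 CPM. Ass1, an enzyme of arginine synthesis with the listed copy Gm5424, fell from 4.24 ± 0.52 to 2.39 ± 0.4 CPM. Gucy1a1, a subunit of the nitric oxide receptor guanylate cyclase, stood at 93.8 ± 9.62 CPM in wild type and 94.7 ± 9.18 CPM in the knockout. The numbers adjusted over the list alone were 7 and 5 for general capillaries, 4 and 4 for aerocytes, 7 and 5 for other vessels and 2 and 4 for nitric oxide signalling. Camera called none of them (adjusted p of 0.58 for general capillaries, 0.87 for aerocytes, 0.87 for other vessels and 0.59 for nitric oxide signalling).

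Mitochondrial respiration genes were higher for 25 of 53 members and lower for 4 (28 and 5 adjusted over the list alone). Cox8a and Cox6a1 of complex IV rose by 0.34 and 0.35 on the log2 scale, and Sdhc of complex II fell from 36.9 ± 3.1 to 17.7 ± 1.84 CPM. Camera called the list higher (adjusted p = 0.01; adjusted p = 0.92 with an estimated correlation), the only list called in that direction. The call ended with quantile normalization, with 14 genes higher (adjusted p = 0.29; 0.00475 to 0.923 over all alternatives). Cytosolic ribosomal protein genes rose for 16 and fell for 6 of 54. Rps3 fell from 886 ± 60 to 583 ± 20.2 CPM. Fatty acid metabolism genes rose for 7 and fell for 4 of 35, with the acetyl-CoA carboxylase Acacb rising from 5.02 ± 0.59 to 20.2 ± 2.49 CPM. Cholesterol synthesis genes rose for 1 and fell for 3 of 22. Stard4, a sterol transfer protein, rose from 39.8 ± 4.26 to 58.3 ± 8.12 CPM. Hypoxia and glycolysis genes rose for 8 and fell for 10 of 38, and Hif1a, the oxygen-regulated transcription factor, rose from 98.8 ± 2.94 to 147 ± 8.41 CPM. For these 4 lists the counts adjusted over the list alone were 16 and 7 for ribosomal proteins, 7 and 4 for fatty acids, 1 and 3 for cholesterol and 9 and 10 for hypoxia. Camera called none of them (adjusted p of 0.17 for ribosomal proteins, 0.8 for fatty acids, 0.078 for cholesterol and 0.8 for hypoxia). Cholesterol genes passed without knockout replicate 1 (adjusted p = 0.00874; 0.00874 to 0.923 over all alternatives) or wild type replicate 3. With quantile normalization 9 ribosomal protein genes rose and 8 fell, with median-ratio scaling 12 rose and 6 fell, and with members that have a near-identical copy left out 2 rose and 2 fell. Cholesterol genes that fell numbered 8 without knockout replicate 1 and 6 with median-ratio scaling or DESeq2. Ribosomal protein genes fell for 2 members without wild type replicate 1 and for 3 without wild type replicate 2.

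Developmental signalling genes moved without a shared direction. Ski, a repressor of TGF-β signalling, fell from 18.7 ± 0.85 to 7.62 ± 0.48 CPM and Smad4, its shared mediator, from 54.2 ± 3.56 to 36.3 ± 1.86 CPM. In that list 6 of 36 genes rose and 3 fell. Notch genes rose for 2, the ligand Jag1 (from 7.07 ± 1.04 to 13 ± 0.81 CPM) and the modifier Mfng, and fell for 3 of 18. In the list of growth factor and retinoid signals of alveolus formation 10 rose and 6 fell of 36. Numbers adjusted over the list alone were 6 and 3 for TGF-β, 4 and 5 for Notch and 12 and 9 for growth factors. Only 3 growth factor genes fell without wild type replicate 3. Without knockout replicate 2, or with median-ratio scaling or quantile normalization, 5 genes fell in the TGF-β and in the Notch list, and 4 Notch genes rose without knockout replicate 4 or with quantile normalization. The camera adjusted p were 0.8 for TGF-β, 0.7 for Notch and 0.64 for growth factors.

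Of the 52 gene lists tested, camera called 1 higher and 8 lower with a preset correlation of 0.01. None was called with an estimated correlation, where 3 had an unadjusted p under 0.05. Other divisions of the 8 libraries into 4 and 4 gave up to 16 called lists, against 9 for the genotypes. For genes called in the larger direction the highest of the other divisions was 6. Median and camera direction had opposite signs for Wnt targets, alveolar type 1 cells, alveolar fibroblasts, myofibroblasts, arterial and lymphatic endothelium, interstitial macrophages, dendritic cells and mesothelium, and mean and camera direction for alveolar type 1 cells, myofibroblasts, dendritic cells, fatty acid metabolism and vasoactive genes.

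**Figure D5:**
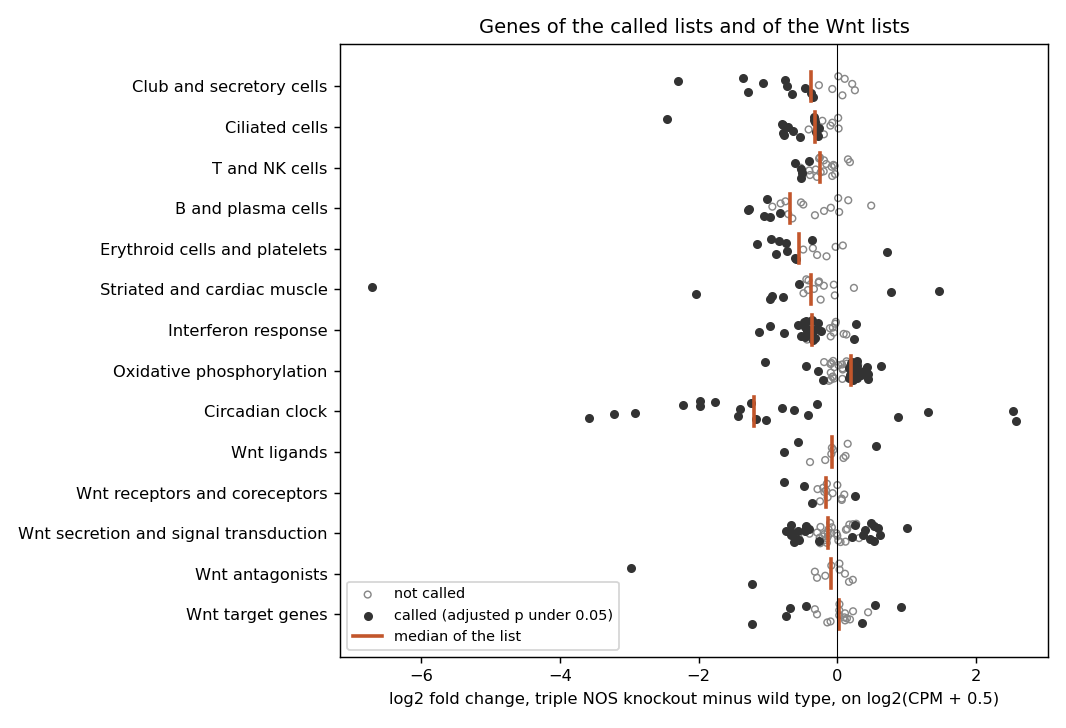
Each dot is the log2 fold change (knockout minus wild type) of a gene in the lists called by camera or in the Wnt lists, filled where the gene was called, with the list median as an orange bar. The clock list had a median of -1.21, the ciliated list -0.33 and the list of Wnt signal transduction -0.13.

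The Y-linked genes were read in all 8 libraries. Ddx3y, called only with median-ratio scaling and with edgeR (adjusted p = 0.0359 to 0.225 over all alternatives), stood at 25.7 ± 2.15 CPM in wild type and 22.4 ± 1.45 CPM in the knockout, Kdm5d at 7.2 ± 0.93 CPM in wild type and 6.55 ± 0.78 CPM in the knockout and Uty at 21.8 ± 1.55 CPM in wild type and 23.3 ± 1.83 CPM in the knockout. Eif2s3y fell from 17.1 ± 0.81 to 12.1 ± 0.3 CPM. A list of genes reported to differ between C57BL/6 substrains or from another laboratory strain was examined gene by gene. CAGE counts transcripts at their start sites, so equal counts do not show equal sequence further along a transcript. Nnt, a mitochondrial enzyme, stood at 7.05 ± 1.11 CPM in wild type and 7.8 ± 0.63 CPM in the knockout. Cyfip2 stood at 7.34 ± 1.18 CPM in wild type and 6.15 ± 0.71 CPM in the knockout and Fgfbp3 at 4.44 ± 0.38 CPM in wild type and 3.76 ± 1.03 CPM in the knockout. Mmrn1 stood at 8.73 ± 0.82 CPM in wild type and 8.11 ± 1.2 CPM in the knockout and Il3ra at 15 ± 0.46 CPM in wild type and 16.4 ± 2.46 CPM in the knockout. Wdfy1 rose from 13.3 ± 1.89 to 34.8 ± 3.22 CPM (adjusted p = 9.08e-06). Ide, Nlrp12 and Plk5 lay below the filter, with means of 0.22, 0.1 and 1.26 CPM in wild type and 0.14, 0.05 and 0.63 CPM in the knockout. Xist, Tsix, Crb1 and Entpd4 were not analysed here.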

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

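The check for a library that stands apart was fixed before the data were examined, and the tests of explanations for the clock genes were all chosen only after the result was seen. For each named gene and genotype, the distance from the most extreme of the 4 libraries to its nearest neighbour was taken as a share of the whole range. A share above Dixon's critical value at 95% for 4 values picked the value out. This happened in 37 of 385 groups of 4 values, where chance alone gives about 5%, or 19.2.

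Knockout replicate 1 was the extreme library in 14 of the 37. Some of these genes were named because they differed in that library, so this number is not an independent tally. It was the lowest knockout library for the cell cycle genes Ube2c (share 0.935, 10.3 CPM against 48.3 to 53.7), Cdc20 (0.947), Prc1 (0.863) and Ccna2 (0.867). The same held for Arntl (0.907), Npas2 (0.834), Nfil3 (0.855), Ces1f (0.97), Stmn2 (0.868) and Gm10709 (0.883). Gm10709 stood at 0 CPM against 0.07 to 0.08 CPM, a step of 1 read, so its share does not show that the library stands apart. It was the highest for Dbp (0.875, 40.3 CPM against 4.69 to 6.21), Tef (0.87), Per3 (0.836) and Dusp1 (0.917).

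Other knockout libraries stood apart for fewer genes. Replicate 2 was lowest for Gpx2-ps1 (0.919) and highest for Chd8 (0.914). Replicate 3 was lowest for Sfrp2 (0.892, 1.59 CPM against 3.51 to 3.84) and Gucy1a1 (0.928). Replicate 4 was highest for Wnt7a (0.871), H2-Aa (0.842), Oasl2 (0.841) and Gm8210 (0.862) and lowest for Tcf7l1 (0.862).

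Among wild type libraries, replicate 1 was lowest for Rspo1 (0.868) and Abcg1 (0.892) and highest for Klf2 (0.835) and Mdm2 (0.94). Replicate 2 was lowest for Cyfip2 (0.858) and H2-Aa (0.855) and highest for Loxl4 (0.924). Replicate 4 was highest for Axin2 (0.842), Scgb1a1 (0.842), Gm6166 (0.862), Gm13841 (0.935) and Atp6v0c-ps2 (0.853), the last at 0.58 CPM against at most 0.06, and lowest for Rgs5 (0.875) and Igfbp3 (0.932).

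The 20 measured clock genes were called, with knockout replicate 1 closer to wild type in their mean shift, each gene turned by its own direction, and with Nr1d1 (85.7 CPM) and Cry2 (26.1 CPM) of that library inside the wild type range. Of the 35 divisions of the 8 libraries into 4 and 4, only 1, the genotypes, gave a mean absolute difference of these genes as large as 1.67 on the log2 scale (highest other 1.22). That value reads no direction. It was largest with the genotypes for 45 of the 52 lists, so it does not set the clock genes apart. Camera, which reads a shift in 1 direction against other genes, gave as small a p in 2 of the 35. Chance is not excluded for its call. With reads thinned to the smallest library 20 clock genes were still called, which argues against depth. All 15 genes of the opposite arms moved in opposite directions, as another time of day at collection may produce, and since no times are given this cannot be told apart from an effect of the genotype on the clock. The genotype remains an untested explanation.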

How the results depend on the processing

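The tests on collapsed entries, thinned reads, omitted copies and divisions of the libraries were chosen only after the result was seen, and the other alternatives before. Under all alternatives 3385 to 4795 genes were called, and all calls shared with the main test had the same direction. Leaving out 1 library gave 1741 to 2387 genes higher and 1552 to 2100 lower. With reads thinned to the smallest library 4174 genes were called, with identical entries collapsed 4282 and without genes that have a copy 3841. The share of higher genes among those called lay between 48.5% and 57.3%, against 53.8%. Of 35 divisions of the 8 libraries into 4 and 4, only 1, the genotypes, reached 2341 genes in 1 direction, and likewise 1 reached 2010. The highest other reached 6. Every other division mixes the genotypes, which widens the spread within its groups, and 1 of 35 is the smallest share this test can give. Chance is thus unlikely for these counts but not excluded.

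The number of lists called by camera moved more. It was 1 higher and 8 lower. With a correlation estimated for each list it was 0 higher and 0 lower. Lists called higher numbered 2 with a pseudocount of 2 CPM, with no filter, with median-ratio scaling and with array weights, the added list being collagens, and 0 with quantile normalization. Leaving out 1 library gave 1 to 4 higher, the 4 without knockout replicate 1, and 8 to 11 lower. The causes were not tested. As many lists as the 9 of the genotypes, both directions together, were called in 19 of the 35 divisions, with up to 16 in another. As many as 8 in the larger direction were called in 11, with up to 11 in another, so chance is not excluded for the list counts. By the mean absolute log2 difference of its genes, which reads no direction, 45 of the 52 lists were largest with the genotypes. So large a share sets no single list apart. For the lists that camera called, its p was as small in 2 (clock, interferon) or 3 (ciliated) of the 35 divisions. It was so in 8 for club cells and respiration, 10 for T and NK and erythroid cells, and 13 for B cells and striated muscle. Chance is not excluded for these calls. By the mean absolute difference, it is not excluded for the other 7 lists. For B and plasma cells 4 of the 35 divisions gave as large a value (0.63, highest other 0.67), for cell cycle 3 (0.78 and 0.83), and for mast cells 8 (0.22 and 0.32). For elastic fibres (0.25 and 0.25), neutrophils (0.42 and 0.42), adipocytes (0.57 and 0.67) and cholesterol synthesis (0.23 and 0.24) it was 2. The robust variance prior was not run for lists, nor were edgeR and DESeq2.

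Of the 193 named genes 176 were called, 161 of them kept the call with any 1 library left out, and 0 reversed. Over genes and alternatives 4099 results were the same, 97 lost the call and 5 gained it; for lists these numbers were 990, 16 and 32. The call of Csnk2b ended with median-ratio scaling, quantile normalization, edgeR and DESeq2, that of Axin2 with median-ratio scaling, edgeR and thinned reads, and that of Nr1d1 with the robust prior, edgeR and DESeq2. Crebbp lost it with no filter, quantile normalization, the robust prior, DESeq2 and thinned reads, Tle2 with DESeq2, Nkg7 with quantile normalization and Cma1 with thinned reads.

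Replicate numbers are shared between the genotypes, but nothing shows that they pair the animals. Deviations of same-numbered libraries correlated at 0.00 to 0.06 and those of other pairs at -0.13 to 0.12, and 1 of 4 wild type and 2 of 4 knockout libraries correlated best with their own number. With the replicate number as a block, 2384 genes were higher and 2014 lower, and 2 lists were called higher and 9 lower. The block ended the calls of Tle2, Crebbp and striated muscle and added Cd79a, collagens, neutrophils and cholesterol synthesis, and 13 B cell genes fell in place of 6.

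Thinning all libraries to the smallest lowered the calls from 4351 to 4174. With these depths and 4 animals per genotype, the simulated comparison recovered 46 of 67 genes changed 1.5-fold, under a spread that was set and not estimated.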

Other observations

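The tests on very large differences and on ciliated genes below were all chosen only after the result was seen, and the gene lists were fixed before. Cell cycle genes rose for 12 and fell for 4 of 31 members (13 and 4 adjusted over the list alone). Among them Ube2c rose from 10.3 ± 1.64 to 40.8 ± 20.5 CPM, Cdc20 from 8.22 ± 0.79 to 27.5 ± 14 CPM, Prc1 from 3.51 ± 0.32 to 15.5 ± 8.27 CPM and Ccna2 from 1.44 ± 0.2 to 5.82 ± 3.11 CPM, genes of cell division named after their values were seen. Mcm6 and Ccne2, which act in DNA replication and its onset, fell, from 21.2 ± 2 to 8.32 ± 0.73 CPM and from 4.28 ± 0.45 to 2.39 ± 0.52 CPM. In 3 of the 35 divisions of the libraries the mean absolute difference of the list was as large as with the genotypes (0.78, highest other 0.83), so chance is not excluded for it. In knockout replicate 1 Ube2c was 10.3 CPM, at the wild type level. Without that library Ube2c rose by 2.26 on the log2 scale, 19 genes of the list rose, and camera called the list (adjusted p = 5.23e-06; 5.23e-06 to 0.926 over all alternatives), against 0.17 with all libraries. The genes that rose numbered 7 without wild type replicate 2 or knockout replicate 4 or with a robust variance prior, and 6 without knockout replicate 3 or at a mean of at least 5 CPM. The call of Cdc20 ended without any library except knockout replicate 1 (adjusted p = 3.14e-07 to 0.102 over all alternatives), and that of Ccna2 without knockout replicate 3 or 4 (6.04e-06 to 0.0584). With a robust variance prior neither of them passed, nor did Ube2c and Prc1.

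Genes of senescence, p53 and apoptosis rose for 11 and fell for 3 of 28. Igfbp3, which binds insulin-like growth factors, rose from 33.4 ± 3.42 to 91.8 ± 22.9 CPM, Mdm2, the p53 ubiquitin ligase, from 85.9 ± 4.52 to 122 ± 2.56 CPM, and the cell cycle inhibitor Cdkn2a from 0.6 ± 0.22 to 3.66 ± 1.15 CPM. Camera missed the threshold for this list (adjusted p = 0.076) and called it higher without knockout replicate 1 (adjusted p = 0.0443; 0.0443 to 0.866 over all alternatives). Heat shock and unfolded protein genes rose for 11 and fell for 1 of 30, including the cochaperone Bag3 (from 34.6 ± 2.9 to 54.6 ± 3.13 CPM) and Pdia3. Those that rose numbered 6 without wild type replicate 1 or knockout replicate 3 and 7 without wild type replicate 4, and with quantile normalization 8 rose and 3 fell. Glucocorticoid target genes rose for 8 and fell for 5 of 21, with the kinase Sgk1 going from 79.6 ± 4.96 to 122 ± 13.3 CPM and Angptl4 from 18.3 ± 6.34 to 56.1 ± 14.9 CPM. Only 5 of them rose without knockout replicate 3, and 3 fell without wild type replicate 2. Immediate early genes rose for 5, among them Dusp1 and Klf2, and fell for 2 of 29, with 3 higher without knockout replicate 3.

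Vasoactive genes rose for 8 and fell for 3 of 29. Ramp1, a partner of the calcitonin gene-related peptide receptor, fell from 82.8 ± 8.75 to 39.5 ± 1.93 CPM, and the vasodilator peptide Adm rose from 4.4 ± 0.56 to 10.5 ± 4.32 CPM. The mean log2 fold change of this list was -0.13 and its camera direction up. Nerve and neuroendocrine genes rose for 3 and fell for 1 of 8 (Stmn2 rose, S100b fell), and thymus genes for 2 and 1 of 7 (Mns1 rose, Tcf7 fell), with 3 thymus genes lower without knockout replicate 1 and 1 higher when any library except wild type replicate 1 or knockout replicate 3 was left out. Adjusted over the list alone, the counts that rose and fell were 12 and 3 for senescence, 12 and 1 for heat shock, 10 and 5 for glucocorticoid targets, 5 and 2 for immediate early genes, 8 and 3 for vasoactive genes, 3 and 1 for nerve genes and 2 and 1 for thymus genes. Camera called none of them with all libraries, with adjusted p of 0.16 for heat shock, 0.56 for glucocorticoid targets, 0.19 for immediate early genes, 0.58 for vasoactive genes, 0.58 for nerve genes and 0.87 for thymus genes.

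The genotypes differed by more than 2 on the log2 scale for 83 called genes. Of 76 that could be searched, 50 had no near-identical copy, which argues against reads shared between copies as the cause for those. Of the 22 with a listed copy, the sum over the gene and the copies found for it differed by under 1 in 10. Examples were -0.77 for Fabp5 with Gm6166 and 0.07 for Gpx2-ps1 with Gpx2, against -3.51 for Rplp1 with Gm10073. Copies of copies were not joined. Rpl29 with its listed copies gave 0.25, but Gm10709 and Gm13841, each summed without Gm8210, gave -5.83. The count of 10 thus depends on which copies are joined, and for these genes copies stay open. Of those located, 11.8% lay on a chromosome with a Nos gene, against 15% of all genes, which argues against DNA of another strain around the targeted loci as the whole source. With near-identical pairs at separate loci left aside, 23 lay within 10 genes of another in gene order. Over 10000 random draws the mean was 7.9 and the highest value 24 (permutation p = 4e-04). Overlapping genes and less similar related genes side by side were not left aside, and the draws were not matched for them. The excess can thus come from such genes, and it does not decide whether strain DNA at several places contributes. The labels give C57BL/6J as the background of all 8 mice but no breeding history, so they do not decide on this. Of the genes named from the strain check list, Wdfy1 rose from 13.3 ± 1.89 to 34.8 ± 3.22 CPM. Nnt, Cyfip2, Fgfbp3, Mmrn1 and Il3ra were not called. An effect of the genotype stays open and untested.

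Ciliated cell genes fell unevenly. Of the 35 divisions of the libraries only 1, the genotypes, gave a mean absolute difference of the list as large as 0.48 on the log2 scale (highest other 0.33). That value reads no direction and was largest with the genotypes for 45 of the 52 lists. Camera, which reads a shift in 1 direction, gave as small a p in 3 of the 35, so chance is not excluded for the fall. A smaller share of airway tissue in the knockout samples would lower them alike only if no other lung cells express them. This was not measured. Their log2 fold changes ran from -0.80 to 0.02 without Tmem212, the gene farthest from the median. They differed from each other beyond their errors, taken as independent. The heterogeneity Q was 8.5 per degree of freedom over 21 genes, where equal changes give about 1. Unequal falls thus cannot decide for or against such a share. An effect of the genotype on ciliated cells stays open and was not tested.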
